A study of Mus musculus with 24 samples.

How the data were processed

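RNA sequencing of 24 libraries of murine BCR-ABL1-positive B-cell leukemia cells with floxed Foxo1 and tamoxifen-inducible Cre was analysed from the authors' processed tables, one for each of 4 comparisons of a treated group with its vehicle group. Groups and replicate numbers came from the sample labels, with 3 libraries in each of 8 groups, and every per-library column was matched to a sample by name. Per the submitters' processing notes, STAR 2.7.11b, Salmon 1.1.1, DESeq2 1.44.0 and the mouse genome build mm10 were used, with no statement of which step each served. Strandedness and the counting rule are not given in the sources used here, so antisense, overlapping and near-identical genes are uncertain.

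Each deposited table held 41444 genes. Of these, 20000 had values and 21444 stood at 0 in every library. The per-library columns and the mean column hold the authors' log2 expression values, deposited after normalisation with a transformation that the file headers do not name. The deposited fold change is a log2 value made by the authors, per the file headers, and the tables also hold the authors' test statistic, a score, and their p-value and adjusted p-value, per the file headers. Over genes at or above the median that passed in the authors' test and in the re-fit, the median ratio of the difference between library values to the deposited log2 fold change was 0.661 in the compound table at 48 h, 0.662 in the 4-OHT table at 24 h and 0.656 in the 4-OHT table at 48 h, so that for these genes differences of library values were smaller than the deposited ones, and the cause was not tested. The mean column was identical in all 4 tables, which places the 24 libraries on 1 scale. Since the values are not counts, total counts are unknown and no counting error can be given. The smallest root mean square difference between 2 libraries was 0.144 on the log2 scale, so that no library was a copy of another.

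Genes were kept where the authors' mean value corresponded to a normalised count of at least 10, which left 11470. This filter was chosen once the values were seen not to be counts, in place of edgeR's own. For 15 genes whose symbol was missing or had been turned into a date, the symbol was looked up by identifier. Gene positions came from the GENCODE M21 annotation of GRCm38, the assembly also called mm10, in which 11438 of the 11470 identifiers were found. The design, the alternatives, the gene lists and the rule for naming genes were written before the data were examined. That design called for a count-based test in edgeR, or limma on log2(value + 1) for values that are not counts. As the deposited values already were on a log2 scale, they were used as deposited, without the added 1. limma 3.58.1 in R 4.3.3 fitted the 2 groups of each comparison with a trended empirical Bayes variance, and p-values were adjusted by Benjamini and Hochberg's method over the tested genes. Calls have an adjusted p under 0.05. Differences between the compound and deletion responses, and between times, were tested as contrasts in 1 model of the 4 groups involved. Errors given with ± are standard errors of a difference unless marked SD. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

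The fixed lists, 24 in number, held 595 entries, 465 of them tested, 14 genes being in more than 1 list. They cover FOXO targets, B-lineage genes, mature B and plasma cell genes, beta-catenin targets, MYC targets and ribosome biogenesis, G1/S, G2/M, p53 targets, the BCL2 family, STAT5 and cytokine targets, cholesterol synthesis, glycolysis, oxidative phosphorylation, ATF4 genes, the unfolded protein response, interferon-stimulated genes, autophagy and lysosome genes, AHR and xenobiotic response genes, cytosolic ribosomal proteins and mitochondrially encoded genes. The last 4 lists are markers of myeloid, T and NK, erythroid and stromal or endothelial cells. Lists were tested with camera at the preset inter-gene correlation of 0.01, two-sided, adjusted over the 24 lists of a comparison, then with an estimated correlation and with fry, which asks whether a list's genes move one way on balance.

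The named genes were the FOXO and GSK3 genes, the 8 with the largest rise and the 8 with the largest fall in each comparison, up to 4 members of each list with the smallest adjusted p, and the 5 with the largest difference each way in each contrast. The genes chosen by size had to pass the test, lie at or above the median of tested genes, carry no predicted or clone name and, in the treatment comparisons, show no overlap between the groups' libraries. Some genes that this rule names are not reported here.

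Whether equal replicate numbers mark paired libraries was checked by correlating the deviations of same-numbered libraries from their group means. At 48 h in the compound arm the 3 correlations were 0.15 or higher, at most 0.41, so that arm and time is reported with the replicate number as a block where that changes a call or moves a count by over 1.5 times. In the other 3 comparisons at least 1 correlation was below 0.1. The check set no limit on unlike numbers. At 24 h of the compound arm, compound replicate 3 and DMSO replicate 2 correlated at 0.51, and compound replicate 2 and DMSO replicate 3 at 0.40. Of same-numbered libraries, replicates 1 correlated at 0.46, and every other pair lay between -0.34 and -0.07. Libraries may thus be paired across unlike numbers there, which the labels do not say, and a block by equal numbers would miss such pairs.

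Before use, the test was tested on simulated data with the mean and spread of each comparison, noise independent between genes, and 200 genes shifted by 0.25, 0.5 or 1. At a change of 0.5 on the log2 scale it found 40.3% of changed genes for AS1842856 at 24 h, 64.2% for AS1842856 at 48 h, 91.0% for 4-OHT at 24 h and 71.6% for 4-OHT at 48 h. The alternatives tried were no filter and a stricter filter on low genes, libraries rescaled to equal medians, pseudocounts of 0.1 and 5 on the unlogged scale, the replicate block, all 24 libraries in 1 fit, an adjusted p under 0.01, an absolute log2 difference of at least 1, the authors' deposited calls, and leaving out each library in turn. One alternative, leaving out both replicate 1 libraries of the compound arm at 48 h, was chosen after seeing the data. A re-fit with DESeq2 was planned for counts and was not run, as the deposited values are not counts.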

Results

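RNA from murine B-cell acute lymphoblastic leukemia cells was profiled by sequencing. The cells carried the BCR-ABL1 fusion oncogene, floxed alleles of Foxo1 and a Cre recombinase that becomes active when 4-hydroxytamoxifen (4-OHT) binds it. The 24 libraries fell into 8 groups of 3. In the compound arm, cells received 70 nM AS1842856, a small-molecule FOXO1 inhibitor that the series describes as acting also on the kinase GSK3, or its solvent DMSO. In the deletion arm, cells received 200 nM 4-OHT, which activates Cre, or its solvent ethanol (EtOH). Each treatment was sampled after 24 h and after 48 h, each with its own vehicle group, so no vehicle library served in more than 1 of the 4 treatment comparisons. All values below are the authors' normalised expression values on a log2 scale, which keep no read counts, so the depth of each library is unknown. The median value of the 11470 tested genes lay between 9.16 and 9.23 in every library. The labels do not say that replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

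The first principal component, which held 41.6% of the variance, separated the 6 libraries treated with 4-OHT (16.5 to 33.9) from the other 18 (-18.6 to 1.1). The compound and DMSO libraries did not separate on it. At 24 h, compound replicate 3 lay at -6.0, whereas the other 2 compound libraries lay at -18.6 and -17.1. On the second component, with 13.0% of the variance, the compound libraries at 48 h (11.9 to 13.6) lay above DMSO at 48 h (2 to 4.5). The 2 groups overlapped there at 24 h. The vehicles also parted on it, with EtOH at -15.5 to -10.6 and DMSO at -3.5 to 4.5 over both times. At 48 h, DMSO replicate 1 stood apart on the fourth component at -18.4, with the other 2 DMSO libraries of that time at -6.0 and -5.8.

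Foxo1, the targeted gene (ENSMUSG00000044167, GRCm38 chromosome 3, 52268336 to 52353221, plus strand, protein-coding), was measured first. In the EtOH libraries at 24 h its log2 value was 9.88, 9.84 and 9.80, and in the 4-OHT libraries 8.18, 8.27 and 7.99. At 48 h the EtOH libraries held 10.02, 10.11 and 10.07, and the 4-OHT libraries 8.16, 8.02 and 8.12. Foxo1 thus fell by 1.70 ± 0.07 (log2, SE) at 24 h and by 1.97 ± 0.06 at 48 h (limma, adjusted p = 4.09e-06 and 1.01e-07), with all 3 treated libraries below all 3 vehicle libraries at each time. In the authors' deposited table the remaining Foxo1 level was 0.154-fold of vehicle at 24 h and 0.116-fold at 48 h. The compound libraries held Foxo1 at 9.29, 9.49 and 9.74 at 24 h, against 9.61, 9.74 and 9.71 in DMSO, and at 9.35, 9.15 and 9.05 at 48 h, against 9.70, 9.40 and 9.34. The differences of -0.18 ± 0.12 and -0.29 ± 0.11 did not pass the test (limma, adjusted p = 1.00 and 0.196). With the replicate number as a block, the 48 h difference passed (adjusted p = 0.0152).

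Among the other FOXO genes and the GSK3 genes, Foxo4 was the member that passed the test in any comparison. It rose by 0.34 ± 0.06 after 48 h of 4-OHT (limma, adjusted p = 0.00113) and fell by 0.44 ± 0.09 after 48 h of AS1842856 (adjusted p = 0.0406). The latter call held in 1 of the 6 fits that left out a library, with adjusted p between 0.0454 and 0.150. The 2 responses of Foxo4 differed by -0.79 ± 0.11 (adjusted p = 2.43e-04). Foxo3, Foxo6, Gsk3a and Gsk3b differed by at most 0.14 between treated and vehicle libraries and passed in none of the 4 treatment comparisons.

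**Figure D1:**
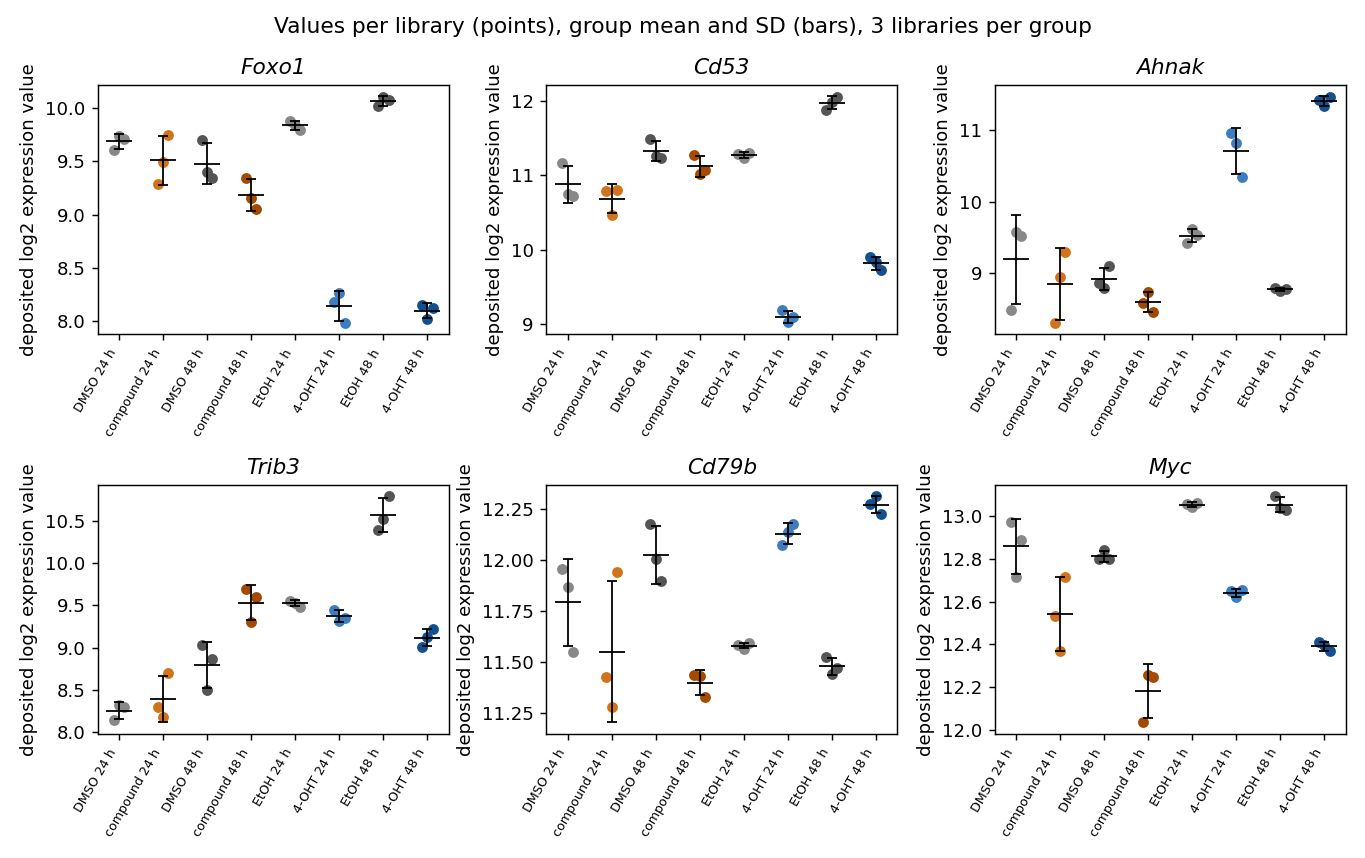
Deposited log2 expression value of 6 genes in each of the 24 libraries (points, 3 per group), with the group mean and SD (bars). Foxo1 lies between 7.99 and 8.27 in the 6 libraries treated with 4-OHT and at 9.05 or above in the other 18.

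The comparison of 4-OHT with EtOH at 24 h asks which transcripts differ within a day of Cre activation. Il7r, a cytokine receptor chain of early B cells, fell by 1.42 ± 0.07, and Cd53, a leukocyte tetraspanin, fell by 2.17 ± 0.05. Ccr7, a chemokine receptor of lymphocyte homing, rose by 1.83 ± 0.06. As lists, genes of ribosome biogenesis were lower, and genes of mitosis, of the lysosome and of the interferon response higher, by camera. None of the 24 lists passed with an estimated correlation, where these 4 had adjusted p from 0.0988 to 0.184.

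Of the 11470 tested genes, 3381 passed (limma, adjusted p under 0.05), 1804 higher and 1577 lower with 4-OHT. With libraries rescaled to equal medians the numbers higher and lower were 1609 and 1938, and among genes with a mean at or above the median 963 and 1215, so the balance is not settled. The genes with the largest rises also included Pld4, an endolysosomal nuclease (1.74 ± 0.07), Clec2i, a C-type lectin (1.49 ± 0.06), Hvcn1, a proton channel (1.47 ± 0.06), Lmo2, a LIM-domain transcription cofactor (1.43 ± 0.05), Lsp1, an actin-binding protein of leukocytes (1.41 ± 0.04), Snn (1.39 ± 0.04) and Pqlc3 (1.35 ± 0.07). The largest falls were those of the T-cell receptor gamma constant genes Tcrg-C1 (-2.44 ± 0.05) and Tcrg-C2 (-2.35 ± 0.03), near-identical copies whose reads cannot be told apart with certainty. They were followed by Slc5a9, a sugar transporter (-2.19 ± 0.04), Camk2d, a calcium-dependent kinase (-1.60 ± 0.04), Tgfb3, a TGF-beta ligand (-1.46 ± 0.05), and Car2, a carbonic anhydrase (-1.45 ± 0.05). Each of these genes had an adjusted p of 7.91e-06 or lower and kept its call without any 1 library. None showed overlap between the 3 treated and the 3 vehicle libraries, as the naming rule required.

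Of the 30 tested genes of the MYC target and ribosome biogenesis list, 26 fell at 24 h and none rose (26 adjusted over the list alone). Myc itself, the transcription factor that drives many of them, fell by 0.41 ± 0.03, Srm, the spermidine synthase, by 0.50 ± 0.04, and Nop56, a component of small nucleolar ribonucleoproteins, by 0.38 ± 0.03. The list's median was -0.30 (camera, adjusted p = 1.44e-14, and adjusted p = 0.0988 with an estimated correlation). Of 25 genes of the ATF4-driven stress response, 17 fell and 2 rose (18 and 2 adjusted over the list alone), with Cth, an enzyme of cysteine synthesis, at -0.94 ± 0.09, Chac1, a glutathione-degrading enzyme, at -0.57 ± 0.05, and Asns, the asparagine synthetase, at -0.46 ± 0.03. Their median was -0.21 (camera, adjusted p = 1.27e-06, and 0.184 with an estimated correlation). Of 21 glycolysis genes, 10 fell and 1 rose (11 and 1 adjusted over the list alone, camera adjusted p = 0.00857, and 0.417 with an estimated correlation), with Hk2, a hexokinase, at -0.55 ± 0.05.

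Of 30 genes of G2/M and mitosis, 20 rose and none fell (21 adjusted over the list alone), among them Kif23, a kinesin of the midbody (0.55 ± 0.04), and Nusap1, a spindle protein (0.40 ± 0.03). The median was 0.15 (camera, adjusted p = 1.94e-07, and 0.0988 with an estimated correlation). Of 17 interferon-stimulated genes, 11 rose (15 adjusted over the list alone), with Bst2, an antiviral tether, at 0.96 ± 0.09, and Gbp2, a guanylate-binding protein, at 0.75 ± 0.07 (camera, adjusted p = 3.79e-06, and 0.0988 with an estimated correlation). Of 27 autophagy and lysosome genes, 18 rose (19 adjusted over the list alone), with the lysosomal protease Ctsb at 0.61 ± 0.04 (camera, adjusted p = 3.22e-07, and 0.184 with an estimated correlation). Of 13 genes of mature B and plasma cells, 7 rose and 3 fell (7 and 3 adjusted over the list alone), with Tnfrsf13c, the BAFF receptor, at 1.29 ± 0.04, and Xbp1, a secretory-cell transcription factor, at 0.65 ± 0.03 (camera, adjusted p = 0.0168, and 0.471 with an estimated correlation).

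Some markers of other blood cells also moved, though most members of the T and NK and the myeloid lists were not tested. Of 5 tested T and NK cell markers 4 rose (4 adjusted over the list alone), including the T-cell receptor kinases Lck (1.34 ± 0.04) and Zap70 (1.05 ± 0.10), with camera adjusted p = 8.21e-04, and 0.228 with an estimated correlation. Of 4 tested myeloid markers 3 rose (4 adjusted over the list alone), including Lyz2, a lysozyme (0.86 ± 0.10), with camera adjusted p = 0.0118, and 0.184 with an estimated correlation. Over the 24 libraries Lck had a mean log2 value of 10.9, whereas Lyz2 (6.71), Zap70 (6.59) and Csf1r, the receptor of a macrophage growth factor (3.40), lay below the median of tested genes. Csf1r lay close to the filter on low genes. The lists of FOXO targets and of B-lineage genes had members going both ways, 10 up and 5 down of 31 (13 and 7 adjusted over the list alone) and 13 up and 10 down of 30 (14 and 10 adjusted over the list alone). Neither passed as a list (camera, adjusted p = 0.216 for each). Within the B-lineage list Spib, an ETS-family transcription factor (0.81 ± 0.05), and Cd79b, a signalling chain of the B-cell receptor (0.55 ± 0.03), rose, and Ebf1, a transcription factor that specifies the lineage, fell by 0.63 ± 0.06.

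After 48 h of 4-OHT, Ahnak, a very large scaffold protein, rose by 2.63 ± 0.04, the largest rise among the genes named by size, and Btg2, an antiproliferative gene, rose by 1.95 ± 0.08. Cth, of the ATF4-driven stress response, fell by 2.05 ± 0.08, and Cd69, an early activation antigen of lymphocytes, by 1.43 ± 0.07. As lists, ATF4 genes were lower, and B-lineage, mitotic, lysosomal and interferon-stimulated genes higher, by camera, each with adjusted p = 0.246 with an estimated correlation.

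The test passed 5824 of 11470 genes, 2862 higher and 2962 lower (limma, adjusted p under 0.05), or 3066 and 2788 with libraries rescaled to equal medians. The numbers were 1457 and 2072 among genes with a mean at or above the median. Further rises were those of Snn (2.09 ± 0.06), Ccr7 (2.09 ± 0.08), Pld4 (1.94 ± 0.07), Pqlc3 (1.93 ± 0.04), Bmf, a pro-apoptotic member of the BCL2 family (1.88 ± 0.12), and Lck (1.81 ± 0.06). The further falls were those of Cd53 (-2.15 ± 0.06), Tgfb3 (-2.08 ± 0.04), Tcrg-C2 (-1.89 ± 0.06), Tcrg-C1 (-1.81 ± 0.07), Trib3, a pseudokinase induced by ATF4 (-1.46 ± 0.10), and Cited2, a transcriptional coregulator (-1.42 ± 0.04). Each had an adjusted p of 5.19e-06 or lower and kept its call without any 1 library. None showed overlap between treated and vehicle libraries, as the naming rule required of all but Ccr7.

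Of the 31 tested FOXO targets 16 rose and 5 fell at 48 h (16 and 5 adjusted over the list alone, camera adjusted p = 0.0166, and 0.246 with an estimated correlation). The rises included genes that restrain growth, namely Pik3ip1, an inhibitor of PI3K (1.31 ± 0.06), Ccng2, an atypical cyclin (1.00 ± 0.05), and Cdkn1b, a cyclin-dependent kinase inhibitor (0.60 ± 0.04), and also the pro-apoptotic Bcl2l11 (0.59 ± 0.05). The falls were led by Trib3 and Cited2 and included Il7r (-0.67 ± 0.07). Of 30 B-lineage genes 18 rose and 2 fell (18 and 2 adjusted over the list alone), with Dntt, the terminal transferase of antigen-receptor assembly (1.14 ± 0.05), Spib (1.15 ± 0.04), Cd79b (0.79 ± 0.04), Syk, the kinase of the pre-B-cell receptor (0.65 ± 0.05), and Cd79a (0.57 ± 0.03) among those that rose and Ebf1 (-0.46 ± 0.06) among those that fell (camera, adjusted p = 1.19e-04, and 0.246 with an estimated correlation).

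The MYC target and ribosome biogenesis list had 28 of 30 genes lower (28 adjusted over the list alone), with a median of -0.57, Srm at -1.02 ± 0.05 and Myc at -0.66 ± 0.03. Of 25 ATF4 genes 23 fell and 1 rose (23 and 1 adjusted over the list alone), with a median of -0.77, Chac1 at -1.40 ± 0.07 and Asns at -1.23 ± 0.05. Their camera adjusted p-values were 4.63e-14 and 1.49e-11, and adjusted p = 0.246 with an estimated correlation for each. In glycolysis 15 of 21 genes fell and 3 rose (15 and 3 adjusted over the list alone, p = 2.93e-04, and 0.246 with an estimated correlation), with Eno1, an enolase, at -0.69 ± 0.05. Of 29 nuclear-encoded genes of oxidative phosphorylation 19 fell and 1 rose (20 and 1 adjusted over the list alone, p = 1.88e-04, and 0.434 with an estimated correlation), with Cycs, the soluble cytochrome c, at -0.52 ± 0.04, whereas 7 of 13 mitochondrially encoded genes rose and none fell (7 adjusted over the list alone, p = 0.00553, and 0.434 with an estimated correlation). Of 10 genes of the AHR and xenobiotic response 6 fell (6 lower and 1 higher adjusted over the list alone, p = 0.0427, 0.246 with an estimated correlation, and 0.0716 and 0.0617 without 4-OHT replicate 1 or EtOH replicate 2).

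Mitotic genes were higher at 48 h in 21 of 30 and lower in none (24 adjusted over the list alone, camera adjusted p = 1.88e-06), with Kif23 at 0.63 ± 0.04 and Prc1, a bundler of spindle microtubules, at 0.46 ± 0.04. Interferon-stimulated genes were higher in 15 of 17 (16 adjusted over the list alone, camera adjusted p = 4.18e-06), with Oas3, an antiviral synthetase, at 1.36 ± 0.11, and Irf9, a component of the interferon-activated transcription factor, at 0.90 ± 0.08. Autophagy and lysosome genes rose in 20 of 27 and fell in 1 (20 and 1 adjusted over the list alone, camera adjusted p = 1.88e-06), with Ctsb at 0.77 ± 0.03. These 3 lists had an adjusted p of 0.246 with an estimated correlation. All 4 tested myeloid markers rose (4 adjusted over the list alone, p = 0.00553, and 0.246 with an estimated correlation), Csf1r, close to the filter on low genes, by 1.18 ± 0.07 and Cx3cr1, a chemokine receptor, by 0.97 ± 0.11. Of 5 T and NK cell markers 3 rose (3 adjusted over the list alone, p = 0.0460, 0.316 with an estimated correlation, and 0.0928 and 0.0578 without 4-OHT replicate 3 or EtOH replicate 2).

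The remaining lists did not pass at 48 h of 4-OHT (camera). Adjusted p was 0.0946 for mature B and plasma cell genes (6 up and 2 down of 13, and as many adjusted over the list alone), 0.0759 for STAT5 and cytokine targets (5 up and 11 down of 25, and as many adjusted over the list alone) and 0.148 for the unfolded protein response (3 up and 10 down of 20, and 4 and 11 adjusted over the list alone). It was 0.192 for cytosolic ribosomal proteins (2 up and 9 down of 30, and as many adjusted over the list alone), 0.536 for G1/S genes (6 up and 4 down of 30, and 6 and 2 adjusted over the list alone) and 0.778 for the lists of beta-catenin targets, BCL2 family and cholesterol synthesis (3 up and 4 down of 11, 4 and 5 of 13, and 4 and 7 of 23, with 5 and 6, 4 and 5, and 4 and 7 adjusted over the list alone). It was 0.957 for p53 targets (5 up and 9 down of 23, and 6 and 9 adjusted over the list alone), 0.582 for erythroid markers (1 up and 1 down of 3) and 0.148 for stromal and endothelial markers (1 up of 2), the last 2 with as many adjusted over the list alone. In at least 1 treatment comparison the median, the mean and the test's direction differed in sign for p53 targets, beta-catenin targets, the BCL2 family, mature B cell genes, ribosomal proteins and erythroid markers, and none of these passed there. Among the members Tcf7, a partner of beta-catenin, rose by 1.05 ± 0.08, Etv5, a transcription factor induced by ERK signalling, fell by 1.05 ± 0.05, and Car2 fell by 1.34 ± 0.05.

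The deletion response was compared between 48 h and 24 h in 1 model of the 4 groups. The difference from EtOH widened for Trib3, from -0.15 at 24 h to -1.46 at 48 h, for Cth, from -0.94 to -2.05, and for Ahnak, from 1.18 to 2.63. That of Il7r narrowed from -1.42 to -0.67 (by 0.75 ± 0.11, limma, adjusted p = 0.00104). Much of this lay in the vehicle. From 24 h to 48 h the EtOH mean of Cth rose by 1.20 and that of Trib3 by 1.05, where the 4-OHT means changed by 0.09 and -0.26. The EtOH means of Ahnak and Il7r changed by -0.75 and -0.35, and the 4-OHT means by 0.70 and 0.40. The ATF4 list's median change over that time was 0.32 in EtOH and -0.14 in 4-OHT. These changes within a condition were not tested. H19, a noncoding RNA, was higher by 1.14 ± 0.04 at 24 h and by 0.03 ± 0.03 at 48 h. The responses at both times lay on the same side of 0 for 2695 of the 2727 genes that passed at both times.

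The difference between the times passed for 1790 genes (limma, adjusted p under 0.05), 754 with a higher and 1036 with a lower value at 48 h than at 24 h. With libraries rescaled to equal medians these numbers were 1011 and 776. Ahnak (1.45 ± 0.16), Sp1, a general transcription factor (1.12 ± 0.13), Ighg2b, an immunoglobulin constant gene (1.07 ± 0.08), Tmprss3 (1.04 ± 0.13) and Msh5, a meiotic MutS homolog (0.93 ± 0.11), had the largest positive differences. Trib3 (-1.31 ± 0.12), Cth (-1.11 ± 0.13), H19 (-1.10 ± 0.05), Tubb3, a tubulin (-1.001 ± 0.05), and Gpt2, an aminotransferase (-0.97 ± 0.11), had the largest negative ones. Their adjusted p-values were all 3.83e-04 or lower. Foxo1 itself did not differ between the times beyond the test (-0.27 ± 0.09, adjusted p = 0.0705). By list, 22 of 25 ATF4 genes (23 adjusted over the list alone, camera adjusted p = 4.24e-20) and 19 of 30 MYC and ribosome biogenesis genes (22 adjusted over the list alone, 8.28e-12) had a more negative response at 48 h, and for 13 of 30 B-lineage genes it was more positive and for 1 more negative (17 and 2 adjusted over the list alone, 5.69e-07). With an estimated correlation these were adjusted p = 0.0926, 0.143 and 0.0926.

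AS1842856 at 24 h was compared with DMSO to find the early response to the compound. Morc3, which encodes a chromatin-associated ATPase, passed the test, and no other gene did. Its log2 value was 9.04 ± 0.04 (SD, n = 3) with the compound and 6.22 ± 0.01 with DMSO (limma, adjusted p = 1.07e-05). Morc3 also varied within groups, with an SD of 1.51 in the compound group at 48 h, 1.62 in the DMSO group at 48 h and 1.66 in the EtOH group at 24 h, and its 48 h difference was -0.37 ± 0.92. The lowest values in these groups were 6.227, 6.227 and 6.224, level with DMSO at 24 h, and the highest were 9.1 to 9.2. The small SD of DMSO at 24 h may thus reflect a floor that single libraries of other groups also reached, so the call is uncertain. It was named after its values were seen.

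The count at 24 h of AS1842856 was 1 of 11470 genes, with 232 at an unadjusted p under 0.05 where chance gives 574. In simulated data with the spread of these libraries, the test found 1.49% of genes changed by 0.25 on the log2 scale, 40.3% of those changed by 0.5 and 80.3% of those changed by 1. The simulated noise was independent between genes, so variation that many genes of a library share is left out, and the rates in the real libraries may differ. Over the 557 genes that passed at 48 h, compound replicates 1, 2 and 3 at 24 h carried shares of 0.66, 0.527 and -0.021 of the 48 h response, and the DMSO libraries -0.025 to 0.02, a measure chosen after the data were seen. Without compound replicate 3 the count was 20, without DMSO replicate 1 it was 4 and without compound replicate 2 it was 2. The authors' deposited table called 15 genes at 24 h, of which Morc3 was 1. Myc had an L2FC of -0.46 and an adjusted p of 0.0244 in the authors' deposited table, and here a difference of -0.32 ± 0.10 (limma, adjusted p = 1.00).

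No member of a list passed over all genes at 24 h of AS1842856. Adjusted over the list alone, 1 cholesterol gene and 2 T and NK cell markers were higher and 1 erythroid marker was lower. As whole lists, 11 of 24 passed camera. Cytosolic ribosomal proteins had a median of 0.12 (adjusted p = 2.87e-09), ATF4 genes 0.12 (6.16e-07), glycolysis genes 0.19 (1.82e-05), cholesterol synthesis 0.08 (0.0171), oxidative phosphorylation 0.06 (0.0182) and T and NK cell markers 0.18 (0.0133). B-lineage genes had a median of -0.13 (6.55e-06), G1/S genes -0.05 (8.28e-04), FOXO targets -0.14 (0.00513), interferon-stimulated genes -0.06 (0.0133) and STAT5 targets -0.11 (0.0233). None of the 11 passed with an estimated correlation, where the ATF4 list had the lowest value (adjusted p = 0.138). Cytosolic ribosomal proteins, ATF4 genes and B-lineage genes passed camera without any 1 library. Without compound replicate 1, 2 or 3 the calls lost were those of FOXO targets (adjusted p = 0.181 and 0.229 without replicate 1 or 2), STAT5 targets (0.106 and 0.183), interferon-stimulated genes (0.404 without replicate 1), cholesterol synthesis (0.192 and 0.664 without replicate 1 or 3), and G1/S genes and T and NK cell markers (0.456 and 0.119 without replicate 3). Without DMSO replicate 1 they were G1/S genes (0.294) and T and NK cell markers (0.146), and without DMSO replicate 2 FOXO targets (0.0952), STAT5 targets (0.0961), oxidative phosphorylation (0.279) and interferon-stimulated genes (0.0700). Without DMSO replicate 3 they were glycolysis (0.215) and the oxidative phosphorylation, STAT5 and interferon lists (0.0942 each). The oxidative phosphorylation list had a negative direction without compound replicate 1 (0.418), as had the cholesterol list without DMSO replicate 3 (0.432). Some calls were gained. By camera, those without compound replicate 3 were MYC targets (adjusted p = 1.42e-05), mitochondrially encoded genes (0.0126), AHR genes (0.0278) and G2/M genes (0.0436). Without DMSO replicate 3 they were G2/M genes (0.00578), MYC targets (0.0187) and beta-catenin targets (0.0270), and without DMSO replicate 2 mature B cell genes (0.0499).

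After 48 h of AS1842856, Myc fell by 0.63 ± 0.07, Ccnd3, the D-type cyclin of B-cell precursors, by 0.76 ± 0.05, E2f2, a cell-cycle transcription factor, by 0.53 ± 0.05, Ebf1 by 0.57 ± 0.06 and Cd79b by 0.62 ± 0.07. Jun, a subunit of the transcription factor AP-1, rose by 1.00 ± 0.08, Bhlhe40, a transcriptional repressor, by 0.90 ± 0.10, Zap70 by 1.20 ± 0.14 and Bcl2l11 by 0.41 ± 0.06. Of 25 genes of the ATF4-driven stress response 7 rose, and the list passed camera but not with an estimated correlation (adjusted p = 0.485).

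The test passed 557 of 11470 genes, 216 higher and 341 lower (limma, adjusted p under 0.05). Whether the replicate numbers pair these libraries is not settled. The deviations of same-numbered libraries correlated at 0.15 to 0.41, but those of compound replicate 2 and DMSO replicate 3 at 0.18. With the replicate number as a block 1629 genes passed, 764 higher and 865 lower, including all of the 557. The genes named by size that rose were Gas7, a regulator of cell shape (1.19 ± 0.14), Jun, Pld4 (0.96 ± 0.17), Ttll11, a tubulin-modifying enzyme (0.94 ± 0.09), Prr5, a component of mTORC2 (0.91 ± 0.09), Bhlhe40, Sbk1 (0.90 ± 0.20) and Cd69 (0.75 ± 0.14). Those that fell were Klhl24, a ubiquitin ligase adaptor (-1.08 ± 0.14), Gfra2, a receptor of the GDNF family (-1.07 ± 0.09), Drc7 (-1.04 ± 0.08), Pdcd4, an inhibitor of translation (-1.02 ± 0.19), Cplx2, a regulator of vesicle fusion (-0.93 ± 0.07), Ubald2 (-0.93 ± 0.05), Fbxl20 (-0.92 ± 0.14) and Pik3cg, a catalytic subunit of PI3K (-0.86 ± 0.09). Their adjusted p-values lay between 7.52e-04 and 0.0493, and the compound and DMSO libraries did not overlap for any of them, as the naming rule required. Of the 67 named genes that passed here, 21 kept their call without any 1 library, which include those in the opening sentences on this time, and 46 did not, among them Pld4, Sbk1, Cd69, Pdcd4 and Fbxl20. The count was 166, 161 and 108 without compound replicate 1, 2 or 3, and 901, 192 and 168 without DMSO replicate 1, 2 or 3. The authors' deposited table called 1505 genes at this time, 523 of them among the 557.

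Of 30 B-lineage genes 8 fell and none rose at 48 h of AS1842856 (17 lower and 2 higher adjusted over the list alone), with a median of -0.22 (camera, adjusted p = 5.06e-06, and 0.485 with an estimated correlation). Besides Ebf1 and Cd79b they included Vpreb1, a surrogate light chain of the pre-B-cell receptor (-0.41 ± 0.05), whose reads may be shared with its near-identical copy Vpreb2, and the recombinase gene Rag2 (-0.59 ± 0.09). Rag1, the partner of Rag2, had a difference of -1.49 ± 0.26 (adjusted p = 0.0249) and was named after its values were seen. Of 31 FOXO targets 7 fell and 2 rose (10 and 4 adjusted over the list alone, camera adjusted p = 0.0729, and 0.0108, 0.0233 and 0.0252 without compound replicate 1 or DMSO replicate 2 or 3), with Sesn1, a stress-induced inhibitor of mTORC1 (-0.44 ± 0.06), and Cited2 (-0.37 ± 0.06) lower and Bcl2l11 higher. Rag2, Sesn1, Cited2, Vpreb1 and Rag1 each come from calls with an adjusted p between 0.00860 and 0.0249, and the first 4 lost theirs without at least 1 library, the highest values being 0.0751, 0.0569, 0.0747 and 0.0572.

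Of 30 G2/M genes 5 fell (17 adjusted over the list alone), with Aspm, a spindle-pole protein, at -0.42 ± 0.05, and a median of -0.16 (camera, adjusted p = 1.08e-10, and 0.0358 with an estimated correlation, or 0.430 with the block and an estimated correlation). Of 30 G1/S genes 4 fell (6 adjusted over the list alone), with a median of -0.16 (camera, adjusted p = 1.62e-08, and 0.485 with an estimated correlation). Of 25 ATF4 genes 7 rose and none fell (17 adjusted over the list alone), with a median of 0.35, and Atf3, a stress-induced transcription factor, at 1.16 ± 0.15 (camera, adjusted p = 8.64e-11, and 0.485 with an estimated correlation). Of 21 glycolysis genes 2 rose (11 adjusted over the list alone), with a median of 0.20 (camera, adjusted p = 3.60e-07, and 0.485 with an estimated correlation). Atf3 lost its call without compound replicate 3 (limma, adjusted p = 0.0518).

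Other lists passed camera as well. Cytosolic ribosomal proteins had a median of 0.17 (camera, adjusted p = 3.18e-09), mitochondrially encoded genes 0.14 (0.00567) and the unfolded protein response 0.12 (0.0132), and none of their members passed, over all genes or adjusted over the list alone. Of 10 AHR and xenobiotic response genes 3 rose (5 adjusted over the list alone, median 0.22, 0.0132), and of 5 T and NK cell markers 3 rose (3 adjusted over the list alone, median 0.48, 0.0103), with Cd28, a costimulatory receptor, at 1.41 ± 0.18, a call lost without compound replicate 3 (limma, adjusted p = 0.0562). With an estimated correlation these 5 lists had adjusted p = 0.485. Of 27 autophagy and lysosome genes 2 rose (2 adjusted over the list alone, camera adjusted p = 0.0230, and 0.608 with an estimated correlation). The latter call was lost without compound replicate 1 (0.129) and DMSO replicate 2 or 3 (0.125 and 0.110), and that of the unfolded protein response without DMSO replicate 1 (0.212). With the block, 3 further lists passed camera: mature B and plasma cell genes (adjusted p = 0.0760 without and 0.0275 with the block), MYC and ribosome biogenesis (0.0931 and 0.00779) and cholesterol synthesis (0.0688 and 0.0257). In these 3 lists, 2, 0 and 0 genes rose (3, 0 and 1 adjusted over the list alone) and 0, 1 and 1 fell (0, 1 and 1). Their medians were 0.09, 0.083 and 0.084 with libraries rescaled to equal medians. Without the block they also passed camera when some single libraries were left out. Over these fits adjusted p ran from 0.0201 to 0.233, from 0.00236 to 0.402 and from 0.00110 to 0.471. With the block and an estimated correlation 0 of 24 lists passed.

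The lists of p53 targets (2 up of 23, adjusted p = 0.226), BCL2 family (3 up of 13, 0.539), STAT5 targets (1 up and 4 down of 25, 0.327), beta-catenin targets (1 up and 1 down of 11, 0.972), interferon-stimulated genes (0 of 17, 0.118, but 0.00500 without compound replicate 1) and oxidative phosphorylation (0 of 29, 0.0931, but 0.00961, 0.0291 and 0.0163 without compound replicate 1 or DMSO replicate 2 or 3) did not pass camera at 48 h of AS1842856, nor did myeloid (0.677), erythroid (0.226) and stromal markers (0.285). Adjusted over the list alone, the numbers up and down were 2 and 1, 3 and 1, 4 and 4, 1 and 2, 0 and 0, and 0 and 0 for the first 6, and 0 for each of the markers. Ccnd3 was the STAT5 and cytokine list's member with the lowest adjusted p (0.00174).

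**Figure D2:**
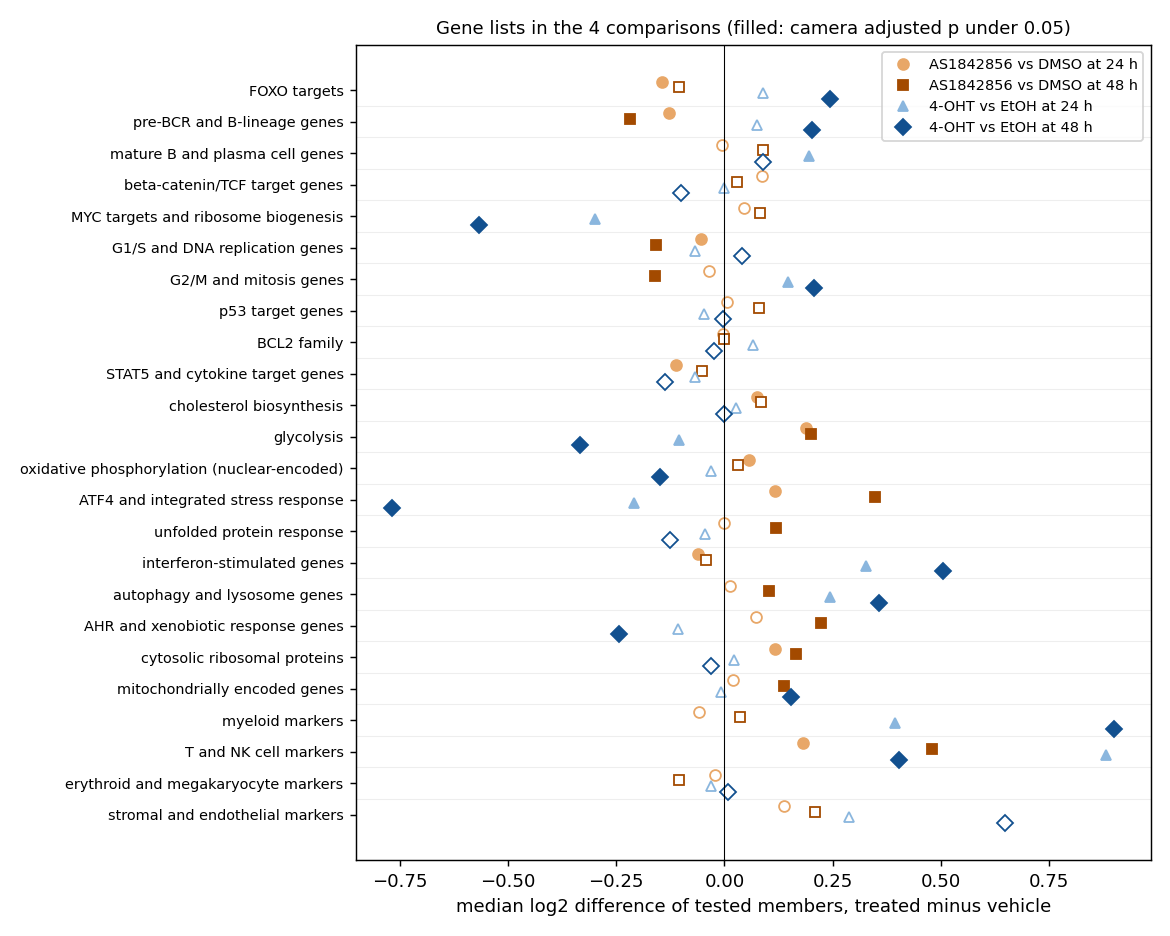
Median log2 difference, treated minus vehicle, of the tested members of each of the 24 gene lists in the 4 treatment comparisons, with filled symbols where camera's adjusted p was under 0.05. The ATF4 list lies at 0.35 after 48 h of AS1842856 and at -0.77 after 48 h of 4-OHT.

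The compound response was also compared between 48 h and 24 h. Jun went from 0.17 at 24 h to 1.00 at 48 h, the difference of 0.83 ± 0.13 having an adjusted p of 0.114 (limma). Atf3 went from 0.35 to 1.16 and Cd69 from 0.07 to 0.75, each with an adjusted p of 1.00. A single gene passed, the predicted gene Gm10698, with -1.23 ± 0.08 (adjusted p = 3.39e-05), and 443 had an unadjusted p under 0.05 where chance gives 574. Gm10698 lay at 3.93 ± 0.09 (SD, n = 3) in the DMSO libraries at 48 h and at 2.71 or lower in the other 9 libraries of the arm, near the lowest values, and was named after its values were seen. Without DMSO replicate 1 of 24 h the count was 4, and without compound replicate 2 of 48 h it was 2. As lists, ATF4 genes (median 0.21) and G2/M genes (-0.16) had the lowest p between the times, each with camera adjusted p = 2.45e-11, and 0.285 and 0.0855 with an estimated correlation. Adjusted over the list alone, 2 ATF4 genes were higher and no G2/M gene differed.

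The comparison of the compound with the deletion asks whether AS1842856 and loss of Foxo1 moved the same transcripts. At 24 h the genes with the largest differences between the responses were ones that had passed with 4-OHT. Il7r differed by -1.42 with 4-OHT and by -0.09 with the compound, and the difference of 1.33 ± 0.20 passed (limma, adjusted p = 0.00167). Cd53 (1.98 ± 0.16), P2ry10, a G-protein-coupled receptor (2.20 ± 0.10), Slc5a9 (1.92 ± 0.26) and the T-cell receptor gamma genes Tcrg-C1 (2.34 ± 0.08) and Tcrg-C2 (2.25 ± 0.08) had the largest positive differences, compound minus deletion. H19 (-1.79 ± 0.24), Lsp1 (-1.62 ± 0.17), Clec2i (-1.60 ± 0.13), Ahnak (-1.52 ± 0.41, adjusted p = 0.0479) and Hvcn1 (-1.51 ± 0.29) had the largest negative ones, 9 of these 10 keeping their call without any 1 library, whereas Ahnak passed in 2 of the 12 such fits (highest adjusted p = 0.113). In all 700 genes passed, 224 with a more positive and 476 with a more negative response to the compound. Groupings that kept the 4-OHT and EtOH groups and mixed the compound and DMSO libraries gave 519 to 2598 genes, a count chosen after the result was seen. The 700 thus mostly measure the response to 4-OHT, and a more positive or negative response to the compound at 24 h is meant relative to 4-OHT. The count was 2037 without compound replicate 3, 408 and 466 without 4-OHT replicate 2 or 3, and 414, 422 and 435 without EtOH replicate 1, 2 or 3.

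By list at 24 h, 12 of 25 ATF4 genes had a more positive response to the compound (17 adjusted over the list alone, camera adjusted p = 5.23e-10, and 0.0102 with an estimated correlation). The vehicles differed there, as the list's median was -0.38 in DMSO relative to EtOH and -0.07 in compound relative to 4-OHT libraries. The same direction held for 5 of 30 MYC and ribosome biogenesis genes (22 adjusted over the list alone, 6.99e-10, and 0.320 with an estimated correlation). A more negative response to the compound was found for 5 of 30 G2/M genes (9 adjusted over the list alone, 1.23e-07, and 0.118 with an estimated correlation) and 6 of 17 interferon-stimulated genes (14 adjusted over the list alone, 3.95e-08, and 0.0704 with an estimated correlation).

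At 48 h several genes moved in opposite directions. Cd79b fell with the compound (-0.62) and rose with 4-OHT (0.79), Cd52, a surface glycoprotein of lymphocytes, likewise (-0.79 and 1.23), and so did Klhl24 (-1.08 and 0.84). Atf3 (1.16 and -1.11), Trib3 (0.74 and -1.46) and Cd69 (0.75 and -1.43) rose with the compound and fell with 4-OHT. The compound call of Trib3 (adjusted p = 0.0391) held in 1 of the 6 fits that left out a library, with adjusted p up to 0.157, and that of Cd69 in 2 of 6, up to 0.125. Myc fell with both (-0.63 and -0.66, difference 0.03 ± 0.08), and Jun (1.00 and 0.79, difference 0.21 ± 0.15) and Bcl2l11 (0.41 and 0.59, difference -0.18 ± 0.07) rose with both, their differences not passing (limma, adjusted p = 0.799, 0.313 and 0.0654).

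The difference between the responses at 48 h passed for 4254 genes (limma), 2064 with a more positive and 2190 with a more negative response to the compound, or 1449 and 1239 among genes with a mean at or above the median. Cth (2.82 ± 0.23), Trib3 (2.19 ± 0.20), Cd69 (2.18 ± 0.17), P2ry10 (2.08 ± 0.14) and Cd53 (1.95 ± 0.12) had the largest positive differences, and Ahnak (-2.95 ± 0.12), Cd52 (-2.02 ± 0.09), Trp53inp1, a p53-induced gene of autophagy (-1.96 ± 0.37), Klhl24 (-1.92 ± 0.15) and Snn (-1.90 ± 0.19) the largest negative ones, with adjusted p at 0.00138 or lower. Of 25 ATF4 genes 24 had a more positive response to the compound (24 adjusted over the list alone, camera adjusted p = 2.39e-17, and 0.130 with an estimated correlation), as had 25 of 30 MYC and ribosome biogenesis genes (26 adjusted over the list alone, 2.84e-10, and 0.364 with an estimated correlation). The response was more negative for 20 of 30 B-lineage genes (24 adjusted over the list alone, 3.86e-08, and 0.308 with an estimated correlation), 14 of 17 interferon-stimulated genes (15 adjusted over the list alone, 8.92e-07, and 0.221 with an estimated correlation) and 25 of 30 G2/M genes (26 adjusted over the list alone, 5.11e-11, and 0.00577 with an estimated correlation, or 0.150 with the block as well). The vehicles differed too: the ATF4 genes had a median of -0.56 in DMSO relative to EtOH at 48 h, and of 0.54 in compound relative to 4-OHT libraries. The B-lineage genes had medians of 0.19 and -0.22 for these.

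Among genes that passed in both treatments at 48 h, 141 of 359 moved the same way and 218 the opposite way. For each of the 218 the difference itself passed. That nearly follows from the choice of genes with opposite calls in the same libraries, and adds no support. By direction, 140 genes were lower with the compound and higher with 4-OHT where independent lists would share 85.1 (Fisher's exact test, two-sided, p = 3.53e-11), and 78 were higher with the compound and lower with 4-OHT against 55.8 (p = 7.14e-04). By the same exact test the rises with both numbered 70 against 53.9 (p = 0.0136) and the falls with both 71 against 88.1 (p = 0.0326). The exact test takes genes as independent, which they are not, so its p-values here and below may be far too small. At an adjusted p under 0.01 (limma) in both comparisons, 22 genes were lower with the compound and higher with 4-OHT against 11.1 (exact p = 7.62e-04). There 13 rose with both against 6.43 (exact p = 0.00786). The other 2 directions did not pass. They held 9 against 6.85 for higher with the compound and lower with 4-OHT (exact p = 0.393), and 16 against 11.8, now an excess, for falls with both (exact p = 0.193). Across all 11470 genes, which are not independent replicates, the log2 differences of the 2 treatments had Pearson's r = 0.007 and Spearman's rho = -0.069 at 48 h, whereas the 4-OHT responses at 24 h and 48 h had r = 0.776. With the block in the compound comparison 392 genes moved the same way and 617 the opposite way. Without compound replicate 1, 2 or 3 the same-way and opposite numbers were 50 and 67, 49 and 66, and 41 and 37. Without DMSO replicate 2 or 3 they were 56 and 79, and 46 and 70. Without DMSO replicate 1 they were 263 and 296.

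**Figure D3:**
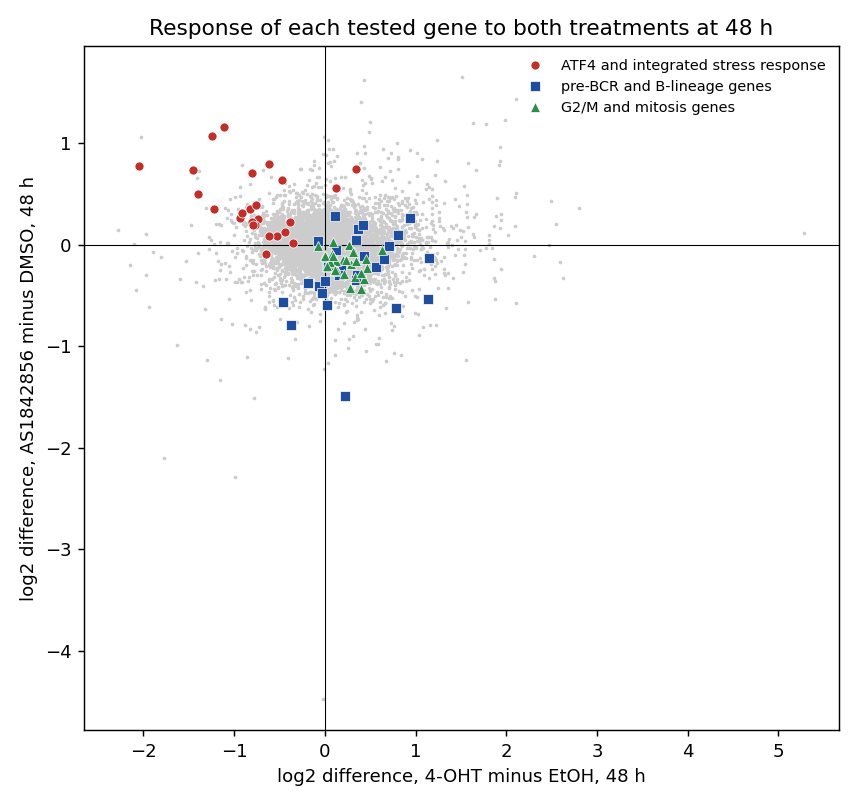
Log2 difference of each of the 11470 tested genes at 48 h, 4-OHT minus EtOH on the horizontal axis and AS1842856 minus DMSO on the vertical axis, with 3 gene lists marked. The ATF4 genes have list medians of -0.77 for 4-OHT and 0.35 for the compound, and the 30 mitosis genes have medians of 0.21 and -0.16.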

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

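The count without compound replicate 3 as an explanation, and the shares of the 48 h response in single libraries at 24 h with their bounds, were tests chosen after the result was seen, and the other tests in this part were planned. Each gene or list result here has a response that differs between 24 h and 48 h by a test of the difference itself, 48 h minus 24 h. The pattern weighed at the end sets counts of calls side by side instead. Groups of 3 are too small for a test of single outlying samples.

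The response to 4-OHT differed between the times for 1790 genes (limma). Among the genes named in the text, those more positive at 48 h were, in order of size, Ahnak (1.45), Sp1 (1.12), Gas7 (1.102), Ighg2b (1.07), Tmprss3 (1.04), Msh5 (0.93), Btg2 (0.90), Csf1r (0.88), Il7r (0.75), Oas3 (0.72), Rag1 (0.70), Snn (0.70) and Trp53inp1 (0.68). They were followed by Dntt (0.66), Tcrg-C1 (0.64), Bmf (0.60), Pqlc3 (0.59), Zap70 (0.58), Pik3ip1 (0.57), Rag2 (0.50), Cx3cr1 (0.48), Lck (0.47), Tcrg-C2 (0.45), Cd52 (0.45), Ccng2 (0.45) and Irf9 (0.45). Next came E2f2 (0.43), Bcl2l11 (0.43), Klhl24 (0.42), Fbxl20 (0.35), Spib (0.34), Sbk1 (0.34), Drc7 (0.31), Camk2d (0.28), Cd79b (0.24), Syk (0.23), Foxo4 (0.22) and Cd79a (0.21). More negative at 48 h were Trib3 (-1.31), Cth (-1.11), H19 (-1.104), Tubb3 (-1.001), Gpt2 (-0.97), Atf3 (-0.90), Chac1 (-0.83), Asns (-0.77) and Cd69 (-0.73). They were followed by Etv5 (-0.66), Tgfb3 (-0.62), Pik3cg (-0.58), Srm (-0.52), Eno1 (-0.42), Cited2 (-0.41), Clec2i (-0.37) and Myc (-0.25).

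By list, 13 passed camera for this difference, with medians of 0.11 for FOXO targets, 0.20 for B-lineage genes, -0.25 for MYC targets, 0.047 for G1/S genes, -0.13 for STAT5 targets, -0.19 for glycolysis, -0.15 for oxidative phosphorylation, -0.48 for ATF4 genes, 0.15 for interferon-stimulated genes, 0.072 for autophagy and lysosome genes, 0.19 for mitochondrially encoded genes, 0.40 for myeloid markers and 0.36 for stromal markers. None of the 13 passed with an estimated correlation, where the lowest adjusted p was 0.0926. Of 100 groupings of the 12 libraries, with treated and vehicle libraries exchanged within each time, 8 gave at least as many genes as the real 1790, the highest other count being 3916, so that chance is not excluded by this count. The 7 other groupings with more genes kept the groups of 48 h intact and mixed those of 24 h, which leaves the 48 h response itself in the difference.

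For the compound the response differed between the times for 1 gene (limma), Gm10698 (-1.23), and for 8 lists by camera. Their medians were -0.098 for B-lineage genes, -0.12 for G1/S genes, -0.16 for G2/M genes, 0.21 for ATF4 genes, 0.12 for the unfolded protein response, 0.089 for autophagy and lysosome genes, 0.05 for cytosolic ribosomal proteins and 0.30 for T and NK cell markers. None of these 8 passed with an estimated correlation, where the lowest adjusted p was 0.0855. Of 100 groupings, 17 gave at least 1 gene and the highest other count was 13, so that chance is not excluded.

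The pattern weighed is that the compound gave 1 gene at 24 h and 557 at 48 h. These counts do not show that the response differed between the times, as the tested difference passed for 1 gene, Gm10698. The planned test came out for a swap of a compound with a DMSO library: the real groups correlated across genes with the 48 h response at r = 0.445, and a grouping that exchanges compound replicate 3 with DMSO replicate 2 more strongly, at r = 0.488. A swap also needs a treated library among DMSO, which the values argue against: over the 557 genes the highest share of the 48 h response in a DMSO library was 0.02, against 0.66 and 0.527 in compound replicates 1 and 2. Compound replicate 3 carried -0.021, so a failed treatment of it, a wrong label or an exchange with an outside sample stays open, and 20 genes passed without it. A smaller early form of the later response in the other 2 may also account for the pattern, as 95.9% of the 557 genes had the same sign at 24 h, against 94.1% in the highest other grouping, with a slope of 0.389 over all 3.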

How the results depend on the processing

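The test that left out both replicate 1 libraries of the compound arm at 48 h was chosen after the data were seen, and the rest were planned; DESeq2 was not run, as the values are not counts. Rescaling the libraries and pseudocounts of 0.1 and 5 left every count within 1.5 times of its reported value, the rescaling moving the median of all genes by at most 0.02 in size. Of 445 results for named genes 439 kept their side of the threshold after rescaling, 380 without a filter and 439 with the replicate block, while 63 lost a call in the fit of all 24 libraries and 59 by the authors' deposited adjusted p, and none of these reversed. For AS1842856 at 24 h the count of 1 became 4 without a filter, 0 with only genes at or above the median mean and 0 in the fit of all 24 libraries (limma, 99 and 845 at an unadjusted p under 0.05), 15 in the authors' deposited table and 1 to 20 without a library. For AS1842856 at 48 h the 557 became 205 without a filter, 1629 with the block, 1220 with all 24 libraries, 98 at an adjusted p under 0.01, 23 with an absolute log2 difference of at least 1, 1505 in the authors' deposited table, 849 without both replicate 1 libraries and 108 to 901 without a library. For 4-OHT at 24 h the 3381 became 2178 with genes at or above the median mean, 2219 with all 24 libraries, 1900 at 0.01 and 130 with the size limit, and for 4-OHT at 48 h the 5824 became 3529 with the higher filter and 245 with the size limit. The difference between compound and deletion at 24 h went from 700 to 425 with the higher filter, 461 with the block, 296 at 0.01, 120 with the size limit and 408 to 2037 without a library, and at 48 h from 4254 to 2688, 2595 and 310 with the higher filter, at 0.01 and with the size limit. The compound's difference between times went from 1 to 9 without a filter, 0 with the higher filter (limma, 200 at an unadjusted p under 0.05) and 1 to 4 without a library, and that of the deletion from 1790 to 755 at 0.01 and 32 with the size limit. The same-way and opposite overlaps of 141 and 218 became 47 and 67 without a filter, 392 and 617 with the block, 264 and 386 with all 24 libraries, 29 and 31 at 0.01, and 324 and 474 in the authors' deposited table. They were 93 and 187 with the higher filter and 244 and 295 without both replicate 1 libraries, and without a library the numbers spanned 41 to 263 and 37 to 296. The size limit of 1 was set on differences of library values. Among genes at or above the median that passed in both tests, these had median ratios of 0.656 to 0.662 to the deposited log2 fold changes. For such genes the limit was thus stricter than the same limit on the deposited values. Higher filters and stricter thresholds leave fewer genes by construction, and for the other changes the cause was not tested. Of 96 list results in the treatment comparisons 43 lost a pass with an estimated correlation, which left 1, at 48 h of AS1842856. The 53 that kept their side were mostly lists that had not passed. With fry 61 kept theirs, 20 lost a pass and 12 gained one. Passes went from 11 to 0 and from 11 to 2 at 24 h and 48 h of AS1842856, and from 9 to 16 and from 13 to 21 for 4-OHT. The direction was opposite to the reported one for oxidative phosphorylation at 24 h of AS1842856 without compound replicate 1 (adjusted p = 0.418, range without a library 2.44e-05 to 0.418), cholesterol synthesis there without DMSO replicate 3 (0.432, range 4.39e-07 to 0.664) and cytosolic ribosomal proteins at 24 h of 4-OHT without 4-OHT replicate 3 (0.0454, range 0.0454 to 0.936). With fry it was opposite for beta-catenin and p53 targets at 24 h of 4-OHT (adjusted p = 0.0439 each) and p53 targets at 48 h (0.0484), and the cause was not tested. Equal replicate numbers correlated at -0.34 to 0.46 at 24 h of the compound arm, -0.01 to 0.06 at 24 h and -0.16 to 0.05 at 48 h of the deletion arm, and the block gave 1, 3352 and 5622 genes there. At 24 h of the compound arm, compound replicates 2 and 3 correlated with DMSO replicates 3 and 2 at 0.40 and 0.51, so the block need not follow any pairing there. Depth is unknown, so what it limits cannot be given.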

Other observations

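The tests of p53 and beta-catenin targets as explanations, both tests on the genes that the authors' deposited table calls at 24 h, and the counts of groupings that keep the deletion groups, were chosen after the result was seen. The other groupings of the samples and the vehicle gap were planned.

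Genes of the ATF4-driven stress response differed between the vehicles. Trib3 was at 9.56, 9.53 and 9.49 in the EtOH libraries at 24 h and at 10.40, 10.53 and 10.80 at 48 h, against 8.13, 8.32 and 8.30 in DMSO at 24 h and 9.03, 8.50 and 8.87 at 48 h. The list's median in DMSO relative to EtOH was -0.38 at 24 h and -0.56 at 48 h. G1/S genes (0.37) and cholesterol synthesis genes (0.33) had the largest positive medians of that difference at 48 h. These differences between the vehicles were not tested, and the labels do not say whether the arms were grown side by side.

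The first pattern weighed here is that 218 of the 359 genes passing in both treatments at 48 h moved in opposite directions. A starting difference between the DMSO and EtOH libraries carried a median share of 0.223 of the difference between the responses (95% bootstrap interval 0.166 to 0.285, 2000 resamples of the genes). By the planned limit this argues against it as the whole cause for these genes as a set. The genes share the same libraries, so the interval leaves out the spread between libraries, and the verdict holds for these libraries only. For the ATF4 list the vehicle median of -0.56 stands against a median difference between the responses of 1.11, so the vehicle carries a larger part there. An effect of Cre or 4-OHT apart from the loss of Foxo1 stays open: p53 targets were not higher as a list (camera, adjusted p = 0.957), and no 4-OHT libraries from cells without Cre or floxed alleles are among these samples. An effect of the compound on GSK3 cannot be told apart either, as the beta-catenin list had an adjusted p of 0.972 over 11 tested genes, and a difference between blocking and losing FOXO1 was not tested.

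The second pattern is that 14 genes called at 24 h of AS1842856 in the authors' deposited table did not pass in the re-fit. The filter is not the cause, as 0 of the 14 lay below it. Detection in only some libraries of a group is argued against for 9 of the 14, whose widest range within a group was 0.11 to 0.61 on the log2 scale, and stays open for the other 5, at 1.08 to 2.68. That 2 of the 14 had overlapping compound and DMSO libraries does not measure it. A difference between the authors' count model and a fit to transformed values stays open and was not tested. Those of the 14 with the lowest deposited adjusted p had deposited log2 fold changes of only 0.028 to 0.067, beside library differences of 0.773 to 1.173. The rest had deposited changes larger in size than their library differences. Why the deposited changes of the former were so small was not tested.

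For a comparison of 3 with 3 libraries the 10 groupings cannot give a share under 0.05. The real and the highest other counts were 1 and 2 for AS1842856 at 24 h, where 4 of the 10 groupings gave at least 1 gene, 557 and 1 for AS1842856 at 48 h, 3381 and 1 for 4-OHT at 24 h and 5824 and 2 for 4-OHT at 48 h, where in each of these 3 only 1 grouping, the real one, reached the count. At 48 h of the compound, 3 other groupings part every same-numbered pair as the real one does, and they called 1, 0 and 0 genes (limma). For the difference between compound and deletion, 4 of 100 groupings reached the 700 genes at 24 h, the highest other count being 2598. At 48 h 1 of 100 reached the 4254, the highest other being 3988. Both shares lie under the planned 0.05. They turn on how many of the drawn groupings kept the deletion groups, so they do not exclude chance for a difference between the responses. These counts mostly measure the deletion response: groupings that kept the deletion groups and mixed only the compound and DMSO libraries gave 519 to 2598 genes at 24 h and 2049 or more at 48 h, and the rest at most 3 and 34. Among the former the real count was reached by 4 of 7 at 24 h and by 1 of 10 at 48 h, too few for a share under 0.05, so nothing is said here of chance in the compound groups alone.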
